A study of Mus musculus with 6 samples.

How the data were processed

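The samples were melanocyte stem cells sorted by fluorescence-activated cell sorting from the skin of male mice, 3 WT and 3 K14-SCF Tg samples, each on its own array. Per the labels' protocols, sorted cells went straight into lysis reagent, RNA was purified on small-scale columns, and 0.5 µg of amplified cDNA was labelled with the dye Cy3. Amplification of RNA from few cells and hybridisation to short probes can raise the spread of weakly expressed genes, so signal over background was followed throughout. Per the file headers, the arrays have 1 colour, the probe design refers to genome build mm9, and spots were read with Agilent Feature Extraction 10.7.1.1, the version that the submitters' processing notes also name.

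Per the file headers, the intensity values used are the processed signal of each spot, background-subtracted and detrended within the array and not normalized between arrays, and the median pixel intensity of the spot and of its local background. The flags per spot (well above background, saturated, outlier) are 0 or 1 values and were taken as deposited, per the file headers. The authors also deposited a value table of the same arrays, whose unit is a linear ratio: set against the scanner files, each array's column equals the processed signal divided by 1 constant (between 1404.6 and 1678 by array, with 100% of values within 0.001 of it), near the array's 75th percentile. The column medians were 0.170, 0.177 and 0.169 for WT replicates 1 to 3 and 0.184, 0.188 and 0.176 for Tg replicates 1 to 3. The values are not centred per gene, so scale and direction are known for this table, and the exact definition of the constant is not given in the sources used here.

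Control spots were left out, leaving 55681 probes. Values were log2 of the processed signal minus the array's 75th percentile of it over these probes, with spots of a probe averaged and outlier spots left out. Probes well above background on at least 3 of the 6 arrays, whatever the genotype, were tested: 47730 probes, after 3 were left out as outliers. The scanner files hold no gene names. Probes were named through the RefSeq accession in the files and a RefSeq gene table of assembly GRCm38.p6, whose build differs from that of the files. Gene positions from this table were used only to order genes for the test of the neighbours of Hpse. Of 29786 probes with such an accession, 28331 matched, giving 21368 genes, the accessions of 1455 probes were not in the table, and 23492 tested probes had no symbol. A gene was represented by its tested probe with the highest mean over all arrays, giving 18385 genes.

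K14-SCF Tg was compared with WT by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, no covariates), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. The prior added 1.91 degrees of freedom to the 4 of the residuals. Where a gene was not well above background on any array of a genotype, the fold was taken against a floor. Per array, that genotype's value was the higher of the probe's own signal and the lowest signal among probes well above background. This floor is not a detection limit. On WT replicate 2 a Hpse probe not above background lay at -6.92 on the log2 scale, where the lowest such signal was -8.3. The resulting fold is therefore not a lower bound. Gene lists were tested by camera with a preset correlation of 0.01, with an estimated correlation and with fry beside it, and with Benjamini-Hochberg adjustment over the 24 lists (14 gene lists, 10 lists of markers of other cell types, each with at least 5 measured members). The lists, the design, the alternatives and the rule for named genes were written before the data were examined. The rule named the 10 genes per direction with the largest change among those that passed, with no overlap of the genotypes and above background in both, filled up by the smallest p among genes with a log2 fold change of at least 1 in size where fewer passed. It added up to 5 genes per direction seen above background in 1 genotype alone (by adjusted p, or by the smallest p if none passed), up to 4 members of each list, and Kitl, Kit, Krt14, Mitf, Tyr, Dct and Cdkn1a. Not every gene that the rule named is printed, and some are not reported here.

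The same steps were tested on simulated data drawn from these arrays' means and spreads. For K14-SCF Tg against WT, with 50 genes changed at each size among 18385, limma recovered 0.4% of changes of 2-fold, 8.4% of 4-fold, 49.2% of 8-fold and 70.4% of 16-fold, with 4 false calls per draw. Camera recovered 20 of 20 simulated lists of 16 genes shifted by -1 on the log2 scale and called 1 of 20 unshifted lists. The simulated genes varied independently and shifted alike, whereas the estimated correlation within the real lists reached 0.291. These 2 rates therefore may not hold for the real lists.

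Alternatives covered normalization between arrays (quantile, median), the deposited values, filters on dim probes (none, all 6 arrays), the slide, the slide row or the replicate number in the fit, the moderation of the variance, array weights, the rule for several probes of a gene, the thresholds, the test of lists and leaving out each array. Slide and row were read from the array's position. A planned background correction by normexp on mean signals, with quantile normalization, was not run, because the scanner files hold median and not mean signals. Normexp with an offset of 50 on median signals followed by quantile normalization, a fit without both arrays of slide row 2 and a fit on the brightest 25% of tested probes were chosen after seeing the data. The figures were drawn with matplotlib 3.10.9.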

Results

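Melanocyte stem cells are the reserve of the pigment lineage in the hair follicle, from which pigment-making melanocytes arise. The series asked how their expression differs between wild-type (WT) mice and K14-SCF transgenic (Tg) mice, in which the keratin 14 promoter drives stem cell factor, the ligand of the receptor KIT, in the basal epidermis. The cells were sorted from the skin of male mice by green fluorescence and low side scatter, and their RNA was amplified, labelled with 1 dye and hybridised to 6 Agilent mouse arrays, 3 for each genotype. Between 43668 (WT replicate 3, 78.4%) and 48540 (Tg replicate 2, 87.2%) of the 55681 non-control probes were well above background on an array, and no spot was saturated (0 on each array). The number of arrays limits the precision of what follows. The labels number the replicates without saying that they came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Expression is given as log2 of the processed signal over the array's own 75th percentile, as mean ± SD over 3 arrays per genotype, and a log2 fold change is Tg minus WT.

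Hpse, which encodes heparanase, the enzyme that cleaves heparan sulfate chains of the extracellular matrix, was higher on the K14-SCF Tg arrays than on the WT arrays. Its level was -7.96 ± 0.19 in WT (SD, n = 3) and -2.17 ± 0.23 in K14-SCF Tg (SD, n = 3), a log2 fold change of 5.78 with an SE of 0.24. It was well above background on 0 of the 3 WT arrays and on 3 of the 3 K14-SCF Tg arrays. Against a floor the change was 50.6-fold. The floor took, per WT array, the higher of the lowest signal among probes well above background and the probe's own signal. This fold is not a lower bound, and its size depended on the background handling. With normexp and quantile normalization together, the fitted log2 fold change of Hpse was 2.28 (SE 0.17). A second Hpse probe, likewise above background in no WT and in every Tg array, was 22-fold higher in Tg against the floor (fitted log2 fold change 4.68, SE 0.62) and did not pass (limma, adjusted p = 0.414). Of 18385 genes tested, Hpse was the 1 gene called (limma, adjusted p = 0.0200), and 0 genes were called lower by limma.

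**Figure D1:**
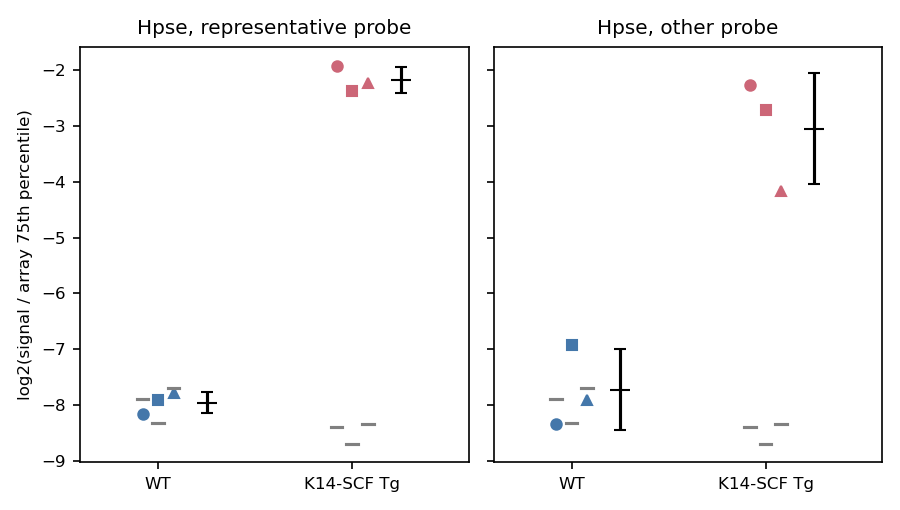
Level of the 2 Hpse probes on each array, as log2 of the signal over the array's 75th percentile. Circles, squares and triangles are replicates 1, 2 and 3, black bars are mean ± SD (n = 3), and grey dashes mark the lowest level among probes well above background on that array. In WT (means -7.96 and -7.73) the probes lie near the grey dashes, except the other probe on WT replicate 2 (-6.92, dash at -8.3). In K14-SCF Tg both lie well above them (means -2.17 and -3.04).

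The genes that came next did not pass the test, and their values are given as such. Among genes without overlap between the genotypes and above background on at least 1 array of each, those with positive log2 fold changes and the smallest p-values included Csrp3, a muscle LIM protein, at 3.16 (SE 0.32), Il10, an anti-inflammatory cytokine, at 4.41 (SE 0.54), and Polr2f, a subunit of RNA polymerases, at 2.03 (SE 0.29). Fcgbp stood at 2.57, Cmtm2b at 5.70, the splicing factor gene Slu7 at 5.32, Lypd3 at 3.12, Srpk3 at 2.86, Egflam at 3.50 and the Polycomb-associated gene Phf19 at 1.72. Il10, Cmtm2b, Slu7, Lypd3, Srpk3 and Egflam were above background on only 1 of the 3 WT arrays, so the size of these differences is uncertain. Of the negative log2 fold changes within the same limits, Shq1, which acts in the assembly of small nucleolar ribonucleoproteins, had the smallest p, at -3.20 (SE 0.31), while its other probe gave -0.93 (SE 1.08) with the genotypes overlapping. Pgm5, a phosphoglucomutase-like protein of cell junctions, stood at -2.44 (SE 0.35), with 3 of its 3 probes negative, and Adamts2, the protease that trims procollagen, at -2.42 (SE 0.38), with -0.53 (SE 0.75) and overlapping genotypes at its other probe. Plppr1 followed at -4.74, Vat1l at -3.59, Zfp839 at -3.29, Rbm20 at -4.09, the centriole duplication gene Stil at -2.58, Mkks at -2.62 and Scrn2 at -1.97. Plppr1, Zfp839 and Rbm20 were above background on only 1 of the 3 Tg arrays. Adjusted p-values of these 20 genes from limma lay between 0.334 (Shq1) and 0.430 (Scrn2). Tspan12, a tetraspanin, was above background on 3 WT arrays and on 0 Tg arrays, 8.52-fold lower in Tg against the floor, and had the second smallest adjusted p of all genes (limma, adjusted p = 0.222). The same pattern of detection, also without passing, held for Car8 (18.7-fold lower against the floor), Ifi205 (19.4-fold) and the activin antagonist Fst (10.1-fold). The pattern of Hpse, above background on 0 WT and 3 Tg arrays, was more frequent than this reverse one. It held, without passing, for Bpifa6 (15.7-fold higher against the floor), Phf11d (17.0-fold) and Agtr1a (18.5-fold), chosen after their values were seen. The lowest level well above background lay between -8.69 and -8.34 on the Tg arrays and between -8.325 and -7.70 on the WT arrays.

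At an unadjusted p under 0.05, limma counted 530 genes higher and 456 lower in K14-SCF Tg, 986 in all, where 919 would come by chance. The 2 genotypes did not overlap in 1942 genes (10.6%, where chance gives 10%). Several tested probes were available for 4858 genes, and in 2204 of these the probes disagreed in sign. WT replicate 1 lay on a slide of its own, and the Hpse call ended within the other slide, which equals the fit with slide as a block (log2 fold change 5.68, limma adjusted p = 0.158), and without any 1 array (5.66 to 5.88, adjusted p between 0.158 and 0.285). It also ended with the slide row as a covariate (5.78, adjusted p = 0.197), with a trended and robust variance (5.78, adjusted p = 0.0582), with the mean of the probes of a gene (5.23, adjusted p = 0.149), without both arrays of slide row 2 (5.90, adjusted p = 0.634) and with another background correction and quantile normalization together (2.28, adjusted p = 0.271).

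The transgene encodes the ligand of KIT, and the pigment lineage genes themselves were measured next. Kitl, the gene of stem cell factor, had a log2 fold change of 0.37 with an SE of 1.31, and its levels split within both genotypes: -3.13, -3.06 and 0.54 on the WT arrays and -2.73, -2.28 and 0.48 on the Tg arrays. Both arrays at the higher Kitl level (WT replicate 3 and Tg replicate 3) lay in row 2 of the slide, all others in row 1, so row and replicate number could not be told apart here. Kit stood at 4.25 ± 0.27 in WT and 3.80 ± 0.34 in Tg (log2 fold change -0.45, SE 0.28). Krt14, whose promoter drives the transgene, had a log2 fold change of 0.14 (SE 0.89). The arrays hold the sorted cells and not the basal epidermis, so Kitl and Krt14 here do not show whether the transgene was expressed there. Differences in Mitf, the master regulator of melanocytes (-0.16, SE 0.32), and in the melanin enzymes Tyr (-0.02, SE 0.26) and Dct (0.11, SE 0.25) were smaller than their errors. Cdkn1a, the p21 cell cycle inhibitor, gave -0.39 (SE 0.46), and its 2 probes disagreed in sign. None of these 7 passed (limma, adjusted p between 0.955 and 1.00).

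**Figure D2:**
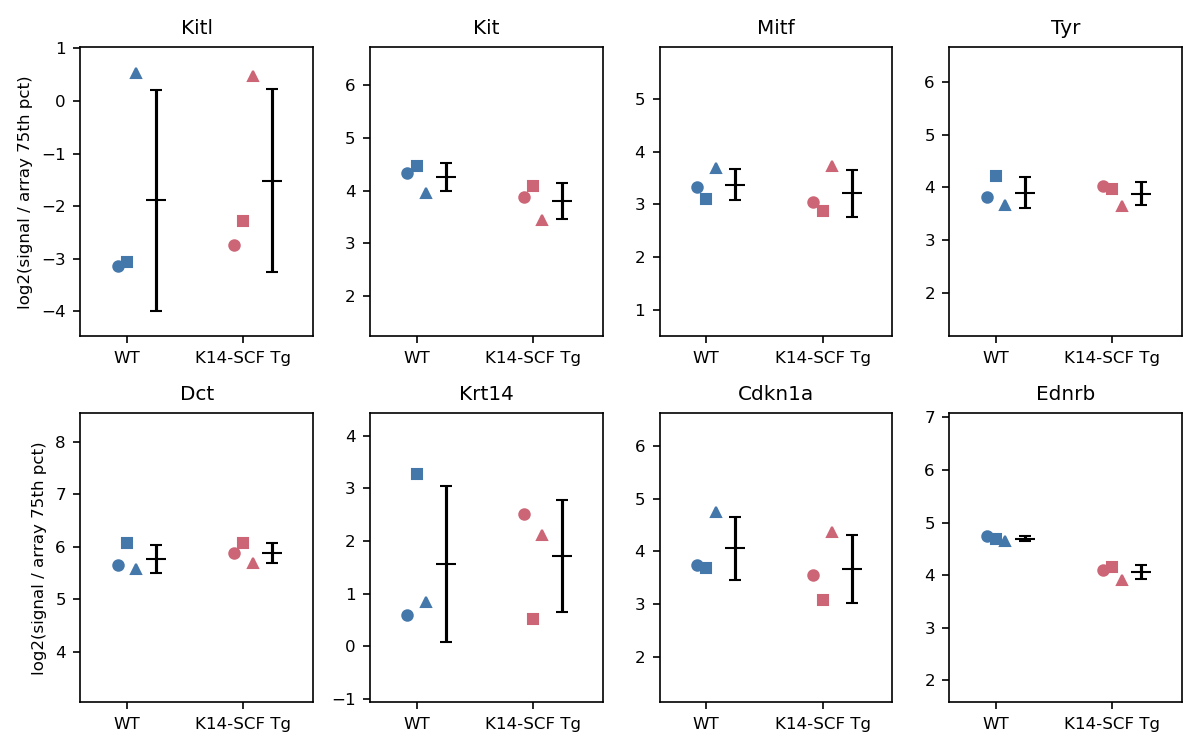
Levels of 8 genes on each array, as log2 of the signal over the array's 75th percentile, on axes of equal length. Circles, squares and triangles are replicates 1, 2 and 3, and black bars are mean ± SD (n = 3). Kitl is higher in replicate 3 of both genotypes (0.54 and 0.48), and Ednrb is 4.70 ± 0.05 in WT and 4.06 ± 0.13 in Tg.

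Of 24 gene lists fixed beforehand, limma's camera called 0 at an adjusted p under 0.05 and 1, the fibroblast markers, at an unadjusted p under 0.05. With an estimated correlation camera called 0, as did fry's directional test, and both also gave 0 lists at an unadjusted p under 0.05. Fry's mixed test, for members that change in either direction, gave unadjusted p = 0.00238 for the senescence genes and 0.0125 for the fibroblast markers. Its p-values were not adjusted over the lists. In none of the lists did a member pass over all genes tested. Adjusted over the list alone, members passed in the senescence genes (1 higher, 1 lower) and the fibroblast markers (1 lower), with 0 in the other 22 lists. This adjustment does not correct for having tested 24 lists, so some members can pass by chance. For each list below, the count of measured members is followed by its median log2 fold change and camera's adjusted p.

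Melanin synthesis and melanosome genes (22 measured) had a median of -0.02 (adjusted p = 0.853), with Rab27a, which carries melanosomes to the cell's edge, at -0.79 and Rab38 at 0.46. Of the 24 melanocyte lineage regulators (median -0.14, adjusted p = 0.557), Ednrb, the endothelin receptor of the lineage, had the smallest unadjusted p, at -0.64 (SE 0.21). Zeb2 stood at -0.53 (-0.04 at its other probe) and Sox9 at 1.11. The mean of this list was positive (0.08), while its median and camera's direction were negative. Genes read as output of KIT and the MAP kinases (24 measured) had a median of -0.06 (adjusted p = 0.557), with the phosphatase gene Dusp5 at -0.87, Epha4 at -0.63 and Ier3 at -0.56. Cell cycle and proliferation genes (27 measured) had a median of -0.09 (adjusted p = 0.557), with Mki67 at -0.93 (0.00 at its other probe) and Ube2c at 1.95.

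The p53 target genes (29 measured) had a median of -0.11 (adjusted p = 0.937), with a mean of 0.05 and an upward direction in camera that went against the median. Tigar, a regulator of glycolysis, stood at 1.02 (SE 0.25), Phlda3 at 1.41 and the DNA damage binding gene Ddb2 at -0.81. Senescence and secretory phenotype genes (21 measured) had a median of -0.26 (adjusted p = 0.557). Adjusted over the list alone, 1 member was higher and 1 lower (smallest limma adjusted p = 0.0277): Cdkn2b, the p15 cell cycle inhibitor, at 2.78 (SE 0.49), and Mmp3, a matrix metalloproteinase, at -2.41 (SE 0.55). This Cdkn2b probe was above background on 1 of 3 WT arrays, and the other gave 1.94 (SE 1.20), with the genotypes overlapping. Igfbp5 (-2.29) and the chemokine Ccl2 (-0.80) did not pass even there. Double-strand break repair genes (22 measured) had a median of -0.17 (adjusted p = 0.557), with Xrcc4 (above background on 2 of 3 arrays of each genotype) at -1.24 and Nbn at 0.57. Arachidonic acid and eicosanoid genes (33 measured) had a median of 0.08 (adjusted p = 0.557), with the phospholipase Pla2g10 at -1.90 and the prostaglandin D synthase Hpgds (above background on 2 of 3 WT arrays) at 2.50.

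TGF-beta response genes (16 measured) had a median of -0.26 (adjusted p = 0.853), and here the mean (0.04) was positive and camera's direction negative. Ccn2 stood at 2.52 and Tgfbi at -1.60. Wnt response genes (15 measured) had a median of -0.04 (adjusted p = 0.853) with a positive mean (0.19) and an upward camera direction, Lgr5 at 2.29 (above background on 2 of 3 WT arrays) and Apcdd1 at -1.40. Interferon response genes (23 measured) had a median of 0.41 (adjusted p = 0.557), with Bst2 at 0.75 and Gbp2 at -0.55. Class I major histocompatibility genes (12 measured) had a median of 0.10 (adjusted p = 0.564), with Psmb9 at 0.41, Tap2 at -0.54 and B2m at 0.15. Immediate early and heat shock genes (19 measured) had a median of -0.15 (adjusted p = 0.557), with Ccn1 at -0.88 and Egr1 at 0.53. Oxidative phosphorylation genes (24 measured) had a median of -0.02 (adjusted p = 0.851), with Ndufs3 at -0.45 and Cox5a at -0.35.

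**Figure D3:**
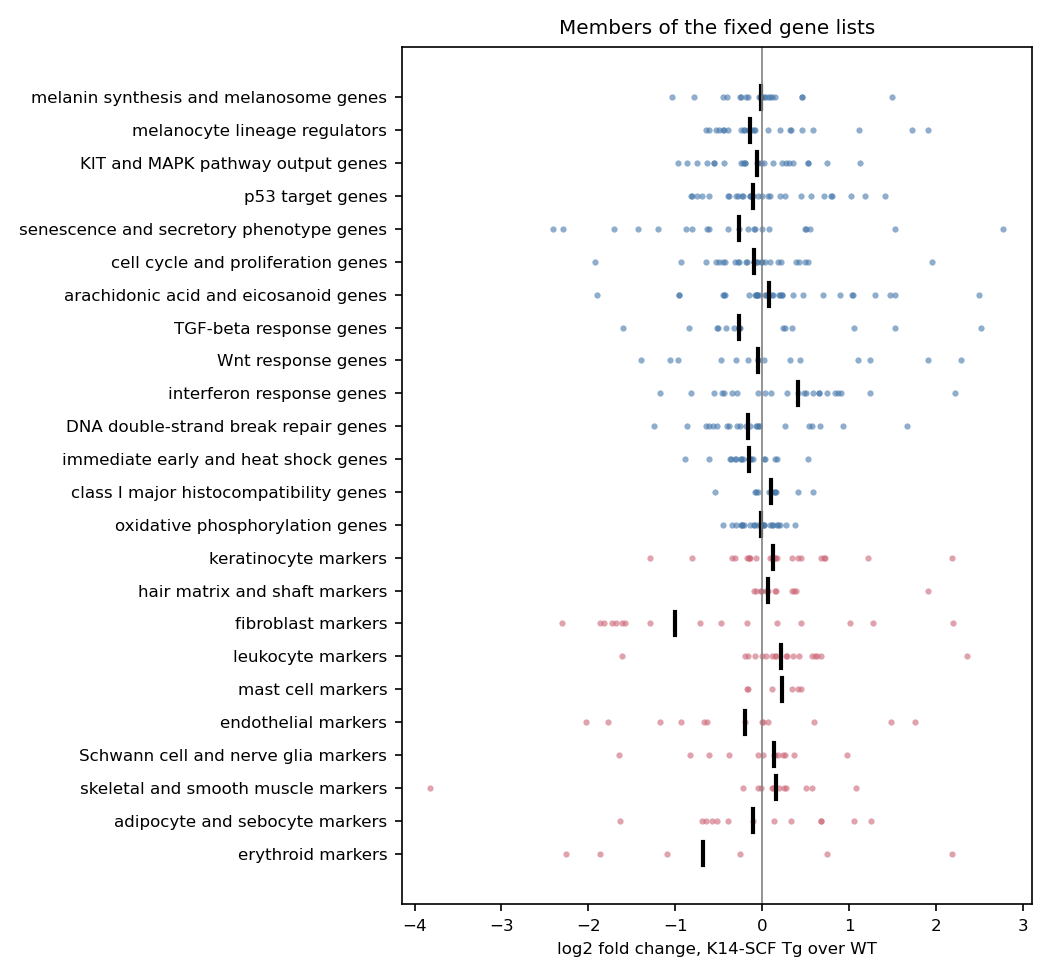
Log2 fold change, K14-SCF Tg over WT, of each measured member (points) of the 24 lists, with the list's median as a black bar. Blue points are gene lists and red points are markers of other cell types. The fibroblast list has the lowest median (-0.998), with 11 of 16 members below 0.

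Markers of other skin cells were measured to describe what the sorts held. The 16 fibroblast markers had the lowest median, -0.998 (mean -0.63, adjusted p = 0.0569), and did not pass. With an estimated correlation the adjusted p = 0.865 and the unadjusted p = 0.0737. Log2 fold changes were negative for 11 members and positive for 5. Collagen genes made up 3 of the 4 named members: Col1a2 stood at 4.49 ± 0.73 in WT and 2.63 ± 0.72 in Tg (log2 fold change -1.86, SE 0.52), Col3a1 at -2.31 (SE 0.76) and Col5a1 at -1.28 (SE 0.44). The surface glycoprotein gene Thy1 (-1.69, SE 0.34) was the 1 member lower when adjusted over the list alone (limma, adjusted p = 0.0436). Fap had the opposite sign (2.20, SE 0.91) and was chosen after its value was seen. Within the slide that holds WT replicates 2 and 3 with all Tg arrays, which equals the fit with slide as a block, the list's median was -0.14 (adjusted p = 0.532), with Col1a2 at -1.55, Col3a1 at -1.84, Col5a1 at -1.10 and Thy1 at -1.67. The list passed without WT replicate 2 (-1.17, adjusted p = 0.0276), without WT replicate 3 (-1.06, adjusted p = 0.0418) and without Tg replicate 1 (-0.94, adjusted p = 0.00564), but not without Tg replicate 2 (-0.52, adjusted p = 0.313) or Tg replicate 3 (-1.01, adjusted p = 0.0887).

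**Figure D4:**
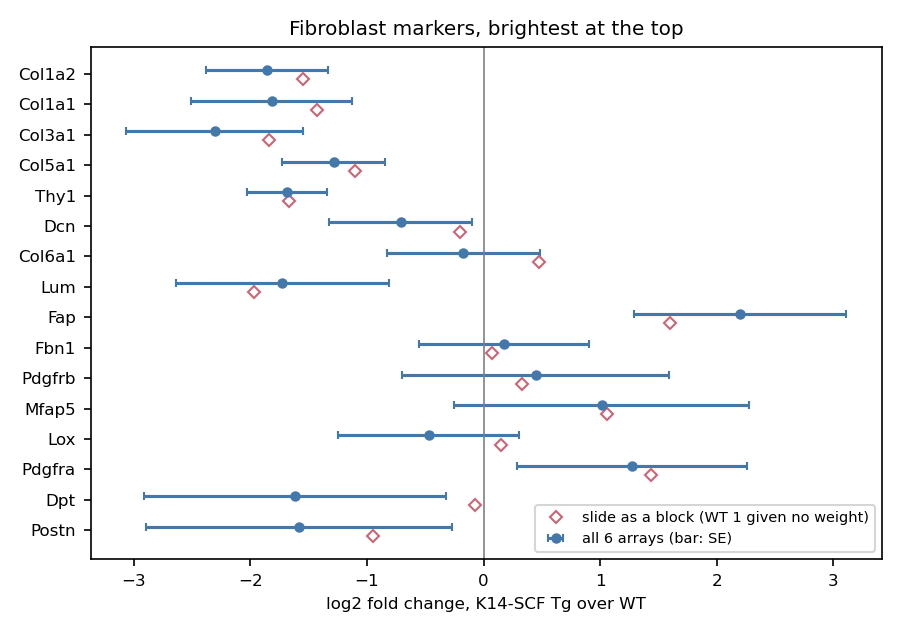
Log2 fold change, K14-SCF Tg over WT, of the 16 fibroblast markers from all 6 arrays (blue, bars are SE) and with the slide as a block (open red), sorted by mean level with the brightest at the top. The 5 brightest members lie between -2.31 and -1.28 with all arrays and between -1.84 and -1.10 with the block.

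Keratinocyte markers (22 measured) had a median of 0.13 (adjusted p = 0.557), with Krt17 at 2.18 (above background on 2 of 3 WT arrays) and Lgals7 at 0.71, and hair matrix and shaft markers (13 measured) a median of 0.07 (adjusted p = 0.557), with Lef1 at 1.91 (-0.31 at its other probe) and Krt28 at 0.39. Leukocyte markers (18 measured) had a median of 0.22 (adjusted p = 0.557), with the invariant chain gene Cd74 at -1.61 and Tyrobp at 2.36. Mast cell markers (6 measured), of interest since mast cells also carry KIT, had a median of 0.23 (adjusted p = 0.557), with the chymase Cma1 at 0.41 and the tryptase Tpsb2 at 0.45 (-0.14 at its other probe). Endothelial markers (13 measured) had a median of -0.20 (adjusted p = 0.557), with Egfl7 at -2.02 and Vwf at -0.94. Erythroid markers (6 measured) had a median of -0.68 (adjusted p = 0.557), with Hbb-b2 at -2.25, and the globin genes Hba-a1 (-1.86, SE 1.47) and Hba-a2 (2.18, SE 1.87) had opposite signs. In 3 marker lists the median, mean and camera's direction differed in sign. Schwann cell and nerve glia markers (13 measured) had a median of 0.14, a mean of -0.09 and an upward direction (adjusted p = 0.882), with S100b at 0.98 and Gfra3 at -1.65 (above background on 2 of 3 WT and 1 of 3 Tg arrays). Skeletal and smooth muscle markers (12 measured) had a median of 0.16, a mean of -0.08 and an upward direction (adjusted p = 0.692), with the pericyte gene Rgs5 at -3.82 (SE 1.51), above background on 1 of 3 Tg arrays. Adipocyte and sebocyte markers (13 measured) had a median of -0.11, a mean of -0.03 and an upward direction (adjusted p = 0.882), with Lpl at -0.69 and Plin4 at 1.05.

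WT arrays were no closer to each other than to K14-SCF Tg arrays. Across tested probes, which are not independent replicates, the correlation of log2 values averaged 0.912 within WT, 0.928 within K14-SCF Tg and 0.918 between the genotypes. The first principal component held 25.9% of the variance between arrays and set WT replicate 3 and Tg replicate 3 apart from the others, and the second held 21.8% and separated the 3 WT from the 3 Tg arrays. The spread between replicates shrank with brightness: the median SD within a genotype was 0.67 in the dimmest 25% of tested probes and 0.31 in the brightest 25%.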

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

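Normexp on median signals with quantile normalization, the fit without slide row 2 and the brightest 25% of probes were tests chosen after the data were seen; all other alternatives were planned, and the planned normexp on mean signals was not run because the files hold no mean signals. Hpse kept its positive direction wherever it was tested. It stayed the 1 gene called, with 0 lower, under quantile normalization, median centring, the deposited values, no filter on dim probes, array weights, an adjusted p under 0.10 and a 2-fold minimum. The count of genes higher and of probes called went to 0 in the other fits, apart from the unadjusted threshold. Hpse then stood at 2.28 with normexp and quantile normalization together, 5.78 with the slide row or with a trended and robust variance, 5.68 with the slide as a block, 5.90 without slide row 2 and 5.23 with the mean of a gene's probes (0 genes called), with limma adjusted p between 0.0582 and 0.634. With probes above background on all 6 arrays, or the brightest 25%, 0 genes and probes were called because Hpse is not in those sets. Over all alternatives its adjusted p ranged from 0.0200 (at the other thresholds, which leave p as it is) to 0.725 with the replicate block. In that fit, with the replicate number as a block, Hpse stood at 5.78 and 0 genes were called; it uses up degrees of freedom, and it changed no list's call. The numbers were not taken to pair the samples: deviations of same-numbered arrays correlated, across probes, with 0.02, 0.05 and 0.13, and not every array correlated best with its own number. Leaving out each array in turn gave 0 genes and 0 probes throughout, Hpse at 5.66 (without K14-SCF Tg replicate 1) to 5.88 (without K14-SCF Tg replicate 2), 0 to 1 lists (the fibroblast markers without WT replicate 2, WT replicate 3 or K14-SCF Tg replicate 1), and a fibroblast median from -1.17 (without WT replicate 2) to -0.14 (without WT replicate 1). At an unadjusted p under 0.05 with a 2-fold minimum, 398 genes were higher, 289 lower, and 1893 probes passed, since no adjustment is made there. The fibroblast markers were the 1 list called with normexp and quantile normalization together (median -0.62, adjusted p = 0.0365), with probes above background on all 6 arrays (-1.28, adjusted p = 0.0256), with the brightest 25% (-1.82, adjusted p = 5.9e-07) and with a trended and robust variance (-0.998, adjusted p = 0.0392). In the brightest 25% the list held only 5 members (Col1a1, Col1a2, Col3a1, Col5a1 and Thy1), so that p rests on few genes. These p-values used camera's preset correlation of 0.01 between members. With an estimated correlation the list of 16 members gave an unadjusted camera p of 0.0737. Over all alternatives the list's adjusted p ranged up to 0.865, with an estimated correlation. The mean correlation within a genotype was 0.920, 0.943 with normexp and quantile normalization together, 0.935 without a filter and 0.931 with probes above background on all 6 arrays. Apart from the sets of probes and the missing adjustment, the cause of these changes was not tested. For 127 other named genes and 23 other lists, 2915 of 2915 values under alternatives kept their side of the threshold. Under at least 1 of them, 10 genes and 12 lists changed direction. The 20 leading genes that did not pass kept theirs, but selection without overlap fixes it in many fits. The spread between replicates was larger at low signal, with a median SD within a genotype of 0.67 in the dimmest 25% of tested probes and 0.31 in the brightest 25%.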

Other observations

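The values on slide row 2, and the tests of a faulty probe, of other cell types, of the fibroblast share, of the slide, and of the splits for genes, probes and genes with several probes were chosen after the result was seen; the tests of neighbouring genes, of spots, of probe pairs and of the splits for the fibroblast list were written before. Among 4858 genes with several tested probes, 46 had each of their probes at an unadjusted limma p under 0.05 in 1 direction, 25 higher and 21 lower in K14-SCF Tg. Those named here were chosen after their values were seen, and apart from Hpse none of the 46 passed the adjusted threshold. Cpe, the prohormone-processing carboxypeptidase E, had 3 such probes, with a log2 fold change of 1.31 (SE 0.21) at its brightest. Runx2 stood at 1.83 (SE 0.49) and the growth factor gene Mdk at 0.97 (SE 0.39). On the lower side, Tnfaip6, a hyaluronan-binding protein, had 3 such probes and stood at -1.79 (SE 0.39), Pgm5 at -2.44 (SE 0.35), Runx3 at -0.73 (SE 0.25) and Dact1 at -1.29 (SE 0.33). Of the 10 splits of the 6 arrays, 3 gave at least 46 such genes, and the highest of the others gave 53. With 10 splits the share cannot lie under 0.05.

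WT replicate 3 and K14-SCF Tg replicate 3, which lie in row 2 of the slide, stood apart from the other 4 arrays more than any other pair did: 4551 probes had an unadjusted limma p under 0.05 between this pair and the rest, against 2993 for the next of the 15 pairs, and 0 passed after adjustment. With genotype in the fit, Kitl was 3.31 higher on the log2 scale on these 2 arrays (SE 0.28, limma adjusted p = 0.263), Cdkn1a 1.04 higher (SE 0.24, adjusted p = 0.404) and Mitf 0.62 higher (SE 0.22, adjusted p = 0.481). In that fit 4761 probes had an unadjusted p under 0.05 and 0 passed after adjustment. Row 2 held only the arrays numbered 3, so the row could not be told apart from the replicate number or from a batch that the 2 samples may share.

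The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split called 1 gene and was 1 of the 10 to call as many, with 0 as the highest of the others. It gave 2609 probes at an unadjusted p under 0.05, 4 of the 10 splits gave as many, and the highest of the others gave 3405. That split sets WT replicate 1 with both arrays of slide row 2. Within the slide that holds both genotypes the real comparison gave 2677 probes, and with the slide row as a covariate 3194. For the fibroblast list the real split gave a camera p of 0.00237, the smallest of the 10 (1 split with a p as small), and the smallest of the others was 0.00391.

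Hpse was not well above background in WT and was well above it in K14-SCF Tg. A fault of 1 probe is argued against by the second probe, also above background on 0 of 3 WT and 3 of 3 K14-SCF Tg arrays. It was 22-fold higher in K14-SCF Tg against the floor (fitted log2 fold change 4.68, SE 0.62). Of the 20 nearest measured genes, by gene order in GRCm38.p6, 1 had an unadjusted limma p under 0.05, the median over 17964 windows of that size. This argues against an altered chromosomal segment with large shifts of many neighbours. Small shifts would seldom reach that p with 3 arrays per genotype. A segment that moves its neighbours little, or holds few of them, therefore stays open. More cells of another type may still contribute: of 10 markers above background on no WT array, 0 were above it on all K14-SCF Tg arrays, 5 of them mast cell markers, but 5 of the 10 lists had no such marker, and a small share of their cells could be hidden by the baseline of their markers. The sort by fluorescence and side scatter is meant to exclude such cells, and the genotype stays open beside this explanation.

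Fibroblast markers had a negative median in K14-SCF Tg against WT, not past the threshold. The separate slide of WT replicate 1, or that sample itself, may account for part of it: with the slide as a block the median of the 13 members above background on all arrays was -0.20, against -1.28 without it. That median is Dcn with the block (-0.71 without) and Col5a1 without it (-1.10 with), so it does not measure how far each member moved. Members moved unevenly: Dpt went from -1.61 to -0.08 with the block, and Lum from -1.73 to -1.97. The slide is argued against as the whole cause for the 5 members among the brightest 25% of probes (Col1a1, Col1a2, Col3a1, Col5a1 and Thy1, of which Col1a1 was chosen after its value was seen), whose median was -1.55 with the block (median SE 0.56) and -1.82 without. The cut by brightness was chosen after the data were seen. These 5 are also the only members with an unadjusted limma p under 0.05 without the block, so the argument covers the top members alone. A smaller share of fibroblasts, which the sort should exclude, or of their RNA stays a candidate explanation for these: the SD of the 13 log2 fold changes was 1.86 times their median SE, between the bounds set for members that fall together and members that go apart, and 0 of the 16 members are in another list. Col1a2 stood at 4.49 in WT, and a lower collagen output of the sorted cells themselves, by genotype, was not tested.

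Replicates spread more at dim than at bright probes. Noise of single spots is argued against by 361 probes printed in 10 spots each: the variance between spots within an array was 0.0331 of the variance of single spots between arrays of a genotype (0.064 for the 175 of them below the median level of tested probes). Differences between the labelled cDNAs may contribute: deviations of 2 probes of the same gene, both below the median level of tested probes, correlated with 0.192 across 1135 genes and all arrays, which are not independent replicates, against at most 0.0586 in 100 shuffles and 0.307 for pairs above that level. That value lies between the bounds set beforehand and leaves the share of the labelled cDNAs open. The design gives no biological explanation for this spread, and none was tested.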
